A study of Mus musculus with 4 samples.

How the data were processed

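RNA was measured in alveolar epithelial type II (AT2) cells sorted by flow cytometry from the lungs of 6-month-old mice. Per the labels' protocols, 1 µg of total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced for 150 cycles on an Illumina HiSeq. The 4 libraries fall into 2 of wild type (WT) and 2 labelled knockout (KO), grouped by sample title. The genotype field of KO replicate 2 names Fbxo46 where that of KO replicate 1 names Fbxo45; the titles put both in the KO group, the growth protocol names Fbxo45 alone, and both genes are reported. Nothing in the labels says whether the 2 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

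The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4, Cuffdiff 2.2.1, Cufflinks and the genome build mm10. Their parameters, the annotation release and the handling of reads that match several places are not given in the sources used here. The deposited table holds 22565 genes, all protein-coding per the file headers, with 1 column of FPKM and 1 column of counts per library. The FPKM values are the authors' fragment values scaled to transcript length and library total, per the file headers, and which length and total they used is not given in the sources used here. The deposited counts are estimated counts, since values need not be whole: each library's values are multiples of 1 constant, and dividing by it made between 90.9% and 92.6% of the positive values whole within 0.05. The fragments recovered in this way sum to 4167115 and 8200169 in the WT libraries and to 9507422 and 7066422 in the KO-labelled libraries. One fragment in the shallowest library is thus a larger share than in the others, and a count of 0 allows up to 0.72 CPM there and 0.316 CPM in the deepest (3 fragments; CPM is here computed from the recovered fragments and their total). Intervals and floors cover counting error only.

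The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(FPKM + 1), KO-labelled minus WT, with no covariate and Benjamini-Hochberg adjustment at 0.05. Genes were tested if they reached 1 FPKM in at least 2 of the 4 libraries, which 11055 did. Differences on the log2(FPKM + 1) scale understate changes of low genes. This design was written for FPKM before the data were examined; because the table also held estimated counts, edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 were run on the recovered fragments, rounded to whole numbers, as alternatives. Gene lists, 40 in number, were also fixed before the data were examined; the 30 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, all two-sided.

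Genes named in the text followed a rule fixed beforehand: Fbxo45 and Fbxo46; per direction the 10 genes past the threshold with the largest change, filled by the smallest unadjusted p where fewer passed; 9 AT2, p53 and proliferation genes; and up to 4 members per list by smallest p. Symbols of predicted genes and pseudogenes were counted and not named, and 1 gene that the rule takes is not reported here. Of the list members, the text gives those of lists that camera called. Genes named outside the rule are said to be so.

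Shared sequence was measured as the percent of sampled 100-base stretches (1 in 4) of a gene's GENCODE M21 transcripts that occur in transcripts of another gene; 96.8% of the table's gene identifiers are in that annotation. Coordinates are from GENCODE M21 (GRCm38, the assembly also called mm10), 1-based. Symbols of 27 genes had been turned into dates in the table, and 166 rows carry a repeated symbol. Gene loci in the table are bundles, and 5875 genes share one with another gene.

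The procedure was tested on simulated data drawn from the libraries' means and sizes at a common dispersion of 0.0845. With 11070 genes tested, limma called 7.41% of genes changed 2-fold, 70.4% of those changed 4-fold and 97.1% of those changed 8-fold. All simulated genes had this same dispersion, whereas real genes may differ in spread, so these shares may be too high for the data. Of random lists of 36 unchanged genes, 2.3% had a camera p under 0.05; simulated genes vary independently, so this says nothing of lists whose members vary together.

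Alternatives covered the pseudocount, the filter, 3 other scalings, the variance model, a replicate block, array weights and leaving out each library. Alternatives of 5 kinds were added after the data were examined: edgeR on recovered fragments, a correction of each library by a loess trend (span 0.3) on GC content and transcript length, leaving out genes with shared sequence, leaving out genes with a shared locus, and an estimated correlation under settings where further lists were called. The fast skeletal and cardiac muscle lists were also written after the data were examined. No isoform rows and no test of the authors' own were used here.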

Results

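The data are RNA profiles of sorted AT2 cells, the surfactant-making cells of the lung alveolus, from 2 WT libraries and 2 libraries labelled KO for Fbxo45, which encodes an F-box protein, the substrate-binding part of a ubiquitin ligase. The design compares KO with WT. Depth was 4167115 and 8200169 estimated fragments in the WT libraries, and 9507422 and 7066422 in KO replicates 1 and 2. Sftpc, which encodes surfactant protein C, took 7.6% and 7.18% of all fragments in the WT libraries and 4.78% and 6.18% in the KO-labelled libraries.

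The targeted gene did not separate the groups. Fbxo45 (ENSMUSG00000035764, chromosome 16, 32230112 to 32247158, minus strand) was at 4.6 and 5.91 FPKM in WT and at 4.41 and 7.58 FPKM in the libraries labelled KO. The group values were 5.25 ± 0.921 FPKM in WT and 5.99 ± 2.24 FPKM in the KO-labelled libraries (SD, n = 2 each). The log2 difference was 0.13 (SE 0.328, limma adjusted p = 0.983), and it was -0.20 without KO replicate 2 and 0.46 without KO replicate 1. Fbxo46 (ENSMUSG00000050428, chromosome 7, 19119859 to 19140172, plus strand), which the genotype field of KO replicate 2 names, was at 4.13 and 3.79 FPKM in WT and at 3.82 and 4.8 FPKM in the KO-labelled libraries. The growth protocol writes cKO for these mice. Which part of Fbxo45 was deleted, and in which cells, is not given in the sources used here, and values per gene do not resolve exons, so they neither bear out the labels nor exclude them. Every direction below is therefore that of libraries labelled KO.

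**Figure D1:**
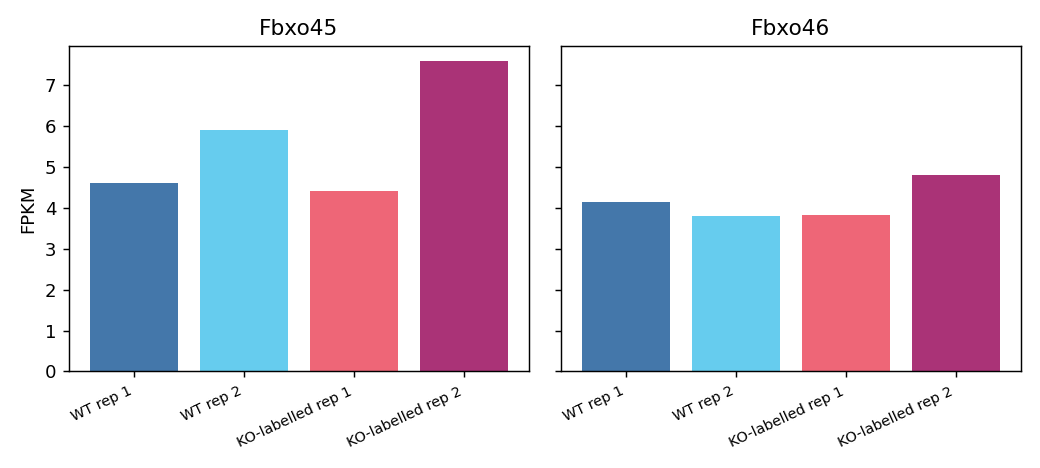
FPKM (vertical axis, from 0) of Fbxo45 and Fbxo46 in each of the 4 libraries, 1 bar per library. For Fbxo45 the KO-labelled libraries, at 4.41 and 7.58 FPKM, lie on both sides of the WT libraries, at 4.6 and 5.91 FPKM.

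No gene passed the threshold between KO-labelled and WT libraries. Of 11055 genes tested with limma, 0 had an adjusted p under 0.05, the lowest adjusted p was 0.947, and 535 had an unadjusted p under 0.05 where 553 would arise with no effect. edgeR on the recovered fragments called 0 of 11705 genes, with 372 at an unadjusted p under 0.05, and DESeq2 called 7, 6 lower and 1 higher in the KO-labelled libraries, with 279 at an unadjusted p under 0.05. The 7 were Map3k11, Ubl4, Pgam2, Rnaseh1, Adnp, Jund and Galnt2, of which Ubl4, Pgam2, Adnp and Jund were chosen after their values were seen. Pgam2, a muscle enzyme and the only higher one, was at 0.909 and 0.458 FPKM in WT, 30.8 FPKM in KO replicate 1 and 2.08 FPKM in KO replicate 2. Adnp was at 20.1 and 19.6 FPKM in WT, 7.84 FPKM in KO replicate 1 and 18.6 FPKM in KO replicate 2. Ubl4 was at 13.49 and 14.13 FPKM in WT and at 4.81 and 2.12 FPKM in KO replicates 1 and 2. Jund was at 69.25 and 50 FPKM in WT and at 22.51 and 26.55 FPKM in KO replicates 1 and 2. Values of Map3k11, Rnaseh1 and Galnt2 are given below. The DESeq2 adjusted p of the 7 ran from 4.37e-12 for Galnt2 to 0.0342 for Rnaseh1. Without KO replicate 2, limma called 134 genes, 72 higher and 62 lower, among them 5 fast skeletal muscle, 6 mitochondrially encoded and 8 replication-dependent histone genes. In 72 of the genes called there, KO replicate 2 lay on the same side of both WT libraries. Such calls favour genes whose WT values lie close together, and by chance a further library would often lie outside such a pair, on either side. Genes with KO replicate 2 on the opposite side were not counted, so this count alone does not bear out the calls. Without WT replicate 2 limma called 3: Mea1 and Galnt2, the former chosen after its values were seen, and 1 predicted gene. In both fits the lone library of a group is assumed to vary like the other pair. The correlation of log2 values over tested genes was 0.971 between the WT libraries and 0.905 between the KO-labelled libraries, the lowest of the 6 pairs.

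None of the genes that follow passed the limma threshold; they had the smallest unadjusted p in each direction. Among those lower in the KO-labelled libraries, Ly6i was at 13.3 ± 2.03 FPKM in WT and 1.39 ± 0.892 FPKM in the KO-labelled libraries (SD, n = 2 each). Tk2, the mitochondrial thymidine kinase, was at 7.76 and 9.08 FPKM in WT and 0.000331 and 1.09 FPKM in the KO-labelled libraries. Rnaseh1, which encodes an enzyme that degrades RNA in RNA-DNA hybrids, was at 2.49 and 3.78 FPKM in WT and was listed at 0.000301 and 0.000421 FPKM in the KO-labelled libraries. Galnt2 was at 20.9 and 7.94 FPKM in WT and 0.545 and 9.81e-14 FPKM in the KO-labelled libraries, and Map3k11 was at 11.5 ± 1.4 and 3.03 ± 0.767 FPKM. Both share a locus with other genes in the table and are uncertain. A second identifier with the symbol Atf7ip (ENSMUSG00000053935) was at 8.64 and 7.82 FPKM in WT and 0.591 and 0.00135 FPKM in the KO-labelled libraries. The first identifier is not described here, so these values do not stand for Atf7ip as a whole. The other 4 of the lower genes were histone genes, described with their list. Among those higher, Thoc6, a component of the THO mRNA export complex, was at 2.81 ± 0.114 FPKM in WT and 9.34 ± 0.149 FPKM in the KO-labelled libraries. Stim2, an endoplasmic reticulum calcium sensor, was at 10.7 ± 0.92 and 24.3 ± 0.548 FPKM. Rps6kb1, the S6 kinase, was at 12.9 ± 0.429 and 27.8 ± 3.44 FPKM. Rrp8, Zfp61, Ptpn4, Sms, Phf12 and RP23-395P6.9 were also among them, with log2 differences from 0.91 for Sms to 2.65 for RP23-395P6.9, which shares 68.8% of its sequence with other genes. Thoc6, Rps6kb1, Rrp8, Ptpn4, Phf12 and RP23-395P6.9 share a locus with other genes and are uncertain. For the higher genes the size differed with edgeR on recovered fragments, which changes unit, scaling and model together, and which of these matters was not tested. There the log2 difference was 0.88 for Thoc6 (1.44 on FPKM), 0.48 for Stim2 (1.12) and 0.27 for Rps6kb1 (1.05), each with an edgeR adjusted p of 0.999. It lay between 0.18 for Ptpn4 and 0.66 for Zfp61 for Rrp8, Zfp61, Ptpn4, Sms and Phf12. RP23-395P6.9 was below edgeR's filter.

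No AT2 identity gene passed the limma test against the spread between libraries. Of 25 tested AT2 markers, 15 were higher and 10 lower, 0 passed over all genes and 0 passed adjusted over the list alone, and camera gave an adjusted p of 0.827. Sftpc was at 98264 ± 4639 FPKM in WT and 71071 ± 23495 FPKM in the KO-labelled libraries (SD, n = 2 each). Sftpa1 was at 8443 ± 35.3 and 8565 ± 1280 FPKM, Sftpb at 10205 ± 332 and 9212 ± 762 FPKM, and Sftpd at 1730 ± 59.1 and 1463 ± 128 FPKM. The lipid transporter Abca3 was at 614 ± 12.5 and 615 ± 75.3 FPKM, and the lung transcription factor Nkx2-1 was at 179 ± 14.7 and 140 ± 29.1 FPKM. The p53 targets Cdkn1a, at 19.1 ± 4.02 and 19.2 ± 6.7 FPKM, and Mdm2, at 16.1 ± 2.19 and 18.4 ± 1.8 FPKM, did not pass it either. The proliferation marker Mki67 was at 0.699 and 1.19 FPKM in WT and at 0.589 and 0.797 FPKM in the KO-labelled libraries, and was below the filter. Of 26 tested p53 target genes 16 were higher and 10 lower (camera adjusted p = 0.827), and of 36 genes of DNA damage signalling and other repair 23 were higher and 13 lower (adjusted p = 0.513).

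The gene list that stood furthest from the rest was that of replication-dependent histones, the core and linker histones made during DNA synthesis. Of 36 tested members 35 were lower in the KO-labelled libraries, 26 had both KO-labelled values below both WT values, 0 passed over all genes and 9 passed adjusted over the list alone. Members under 1 FPKM in both KO-labelled libraries, such as Hist1h4k, passed the filter through WT alone, so their direction was set in advance. Members may also vary together (estimated correlation 0.196), so a chance rate per gene does not apply to these counts. With no filter 51 of 56 were lower, with a median of -0.79. The median log2 difference was -1.18 and camera gave an adjusted p of 2.25e-23. With an estimated correlation the adjusted p was 0.803, and fry gave 0.451. Relative to the WT mean the members' median was -1.50 in KO replicate 1 and -0.69 in KO replicate 2, and without KO replicate 1 the list's median was -0.69. Hist1h3f was at 10.7 ± 1.65 FPKM in WT and 1.28 ± 0.751 FPKM in the KO-labelled libraries. Hist1h3b was at 6.98 ± 1.12 and 1.27 ± 0.65 FPKM, Hist1h4a at 4.91 ± 0.508 and 0.733 ± 0.344 FPKM, and Hist1h4k at 3.05 ± 0.0695 FPKM in WT and listed at 0 in both KO-labelled libraries. Hist1h4k rests on 2 and 4 fragments. The 68 members in the table stood at 430.8 and 437.1 CPM in the WT libraries (exact binomial 95% intervals 411.1 to 451.1 and 422.9 to 451.6). They stood at 179.8 CPM (171.3 to 188.5) in KO replicate 1 and 270.3 CPM (258.3 to 282.7) in KO replicate 2. Many members share sequence with other histone genes and are uncertain. The 6 with at most 5% of shared sequence, 5 of them lower, had a median log2 difference of -0.42 and stood at -0.94 in KO replicate 1 and 0.01 in KO replicate 2. These 6, named outside the rule, differed. Hist1h4d was at 208 and 203.2 FPKM in WT and at 37.18 and 114.1 FPKM in KO replicates 1 and 2. Hist4h4 and Hist1h1d were also below both WT values in both KO-labelled libraries, and Hist2h2be, Hist2h4 and Hist1h1a were not. The 7 with 5 to 25% were all lower, with a median of -0.92, and stood at -0.79 and -0.69 in KO replicates 1 and 2. The 9 with 25 to 50% were all lower as well, with a median of -1.30 (-1.90 and -0.61), and the 10 with more than 50% had a median of -1.37 (-1.75 and -1.34).

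**Figure D2:**
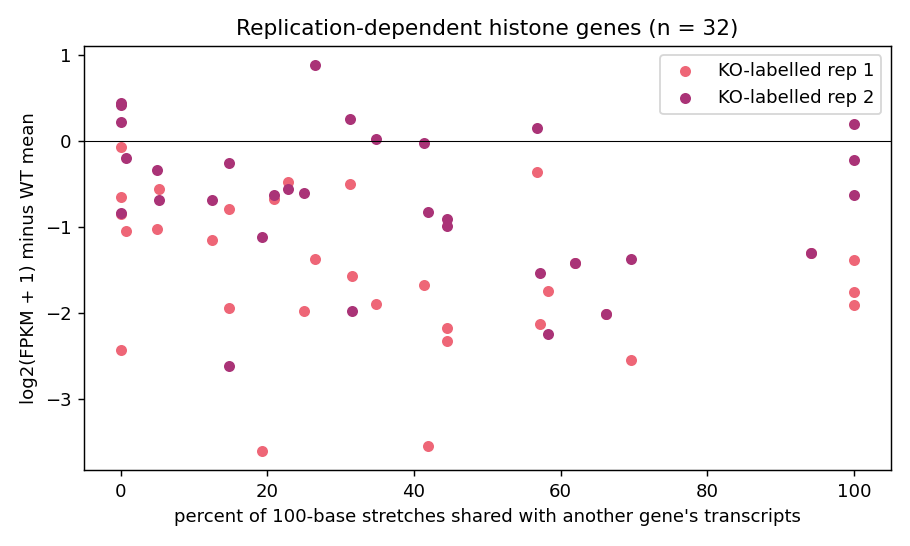
Each point is 1 replication-dependent histone gene in 1 KO-labelled library. The horizontal axis is the percent of its 100-base stretches shared with another gene, and the vertical axis is its log2(FPKM + 1) minus the mean of the WT libraries; the 32 genes with a value of shared sequence are drawn. The 6 genes with at most 5% have a median of 0.01 in KO replicate 2, and the 10 with more than 50% have a median of -1.34 there.

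Camera called 4 further lists at the preset correlation, and with an estimated correlation each had an adjusted p of 0.803. Genes of histone mRNA processing and histone chaperones were higher, 26 of 28, with a median log2 difference of 0.26 and a camera adjusted p of 0.00946. Nap1l1 was at 18 ± 5.41 FPKM in WT and 31.8 ± 5.61 FPKM in the KO-labelled libraries, Daxx at 5.54 ± 0.0403 and 9.87 ± 3.17 FPKM, Rbbp7 at 41.3 ± 6.29 and 56 ± 7.22 FPKM, and Chaf1b at 3.83 ± 0.903 and 5.88 ± 0.5 FPKM. With edgeR on recovered fragments the log2 difference was 0.23 for Daxx (0.70 on FPKM), 0.13 for Rbbp7 (0.43) and 0.28 for Chaf1b (0.52). This call was lost, at medians of 0.22 and 0.25, without KO replicate 2 (adjusted p = 0.132) and without genes that share a locus (0.0942, 15 members). Fibroblast and smooth muscle markers were higher, 16 of 19, with a median of 0.36 and an adjusted p of 0.00946. Mfap5 was at 1.97 ± 0.23 and 5.19 ± 0.787 FPKM, Dcn at 6.27 ± 3.49 and 12.6 ± 1.86 FPKM, Col6a2 at 16.3 ± 0.452 and 25.8 ± 7.8 FPKM, and Bgn at 21.5 ± 15.6 and 35.2 ± 1.31 FPKM. With edgeR the log2 difference was 1.76 for Mfap5 (1.06 on FPKM) and 0.49 for Bgn (0.89). The WT libraries lay 0.51 above and 0.51 below their mean on this list, and without WT replicate 2 its median was -0.096, the opposite direction. The call was lost there and, at a median of 0.30, without KO replicate 1. Without WT replicate 1 the median was 0.81. Wnt and Notch targets were lower, 11 of 13, with a median of -0.15 and an adjusted p of 0.0338. This list also holds Notch receptors and ligands, among them Notch1 and Jag2, so it does not measure pathway output alone. Notch1 was at 27.3 ± 9 and 15.3 ± 3.41 FPKM, Jag2 at 2.78 ± 0.116 and 1.33 ± 0.856 FPKM, Notum at 10.5 ± 3.28 and 6.62 ± 0.0734 FPKM, and Sp5 at 10.6 ± 0.855 and 7.46 ± 1.17 FPKM. With edgeR the log2 difference of Notch1 was -0.47 (-0.77 on FPKM). The list's call was lost, at a median between -0.15 and -0.25, without WT replicate 1 (adjusted p = 0.172), without KO replicate 2 (0.445), with the replicate block (0.0532), with no mean-variance trend (0.0592), with edgeR (0.0786) and with the GC and length correction (0.101). With no filter the median was -0.027 (adjusted p = 0.402). The call held at medians of -0.24 without KO replicate 1, -0.26 with a pseudocount of 0.01 and -0.10 with equal library totals. No member of these lists passed over all genes or adjusted over the list alone.

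**Figure D3:**
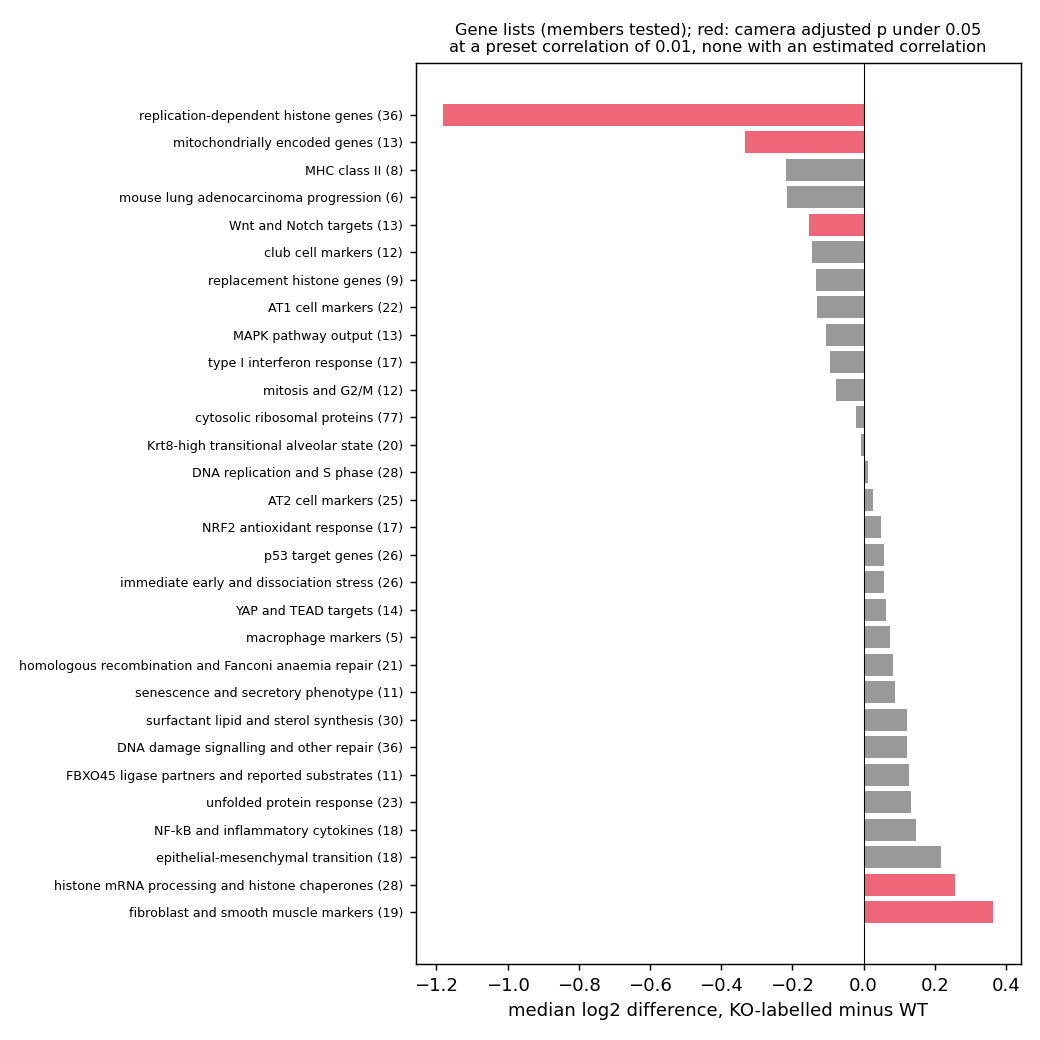
Median log2 difference, KO-labelled minus WT, of each of the 30 tested gene lists, with the number of tested members in brackets. Red bars are the 5 lists with a camera adjusted p under 0.05 at the preset correlation, of which 0 had one with an estimated correlation; the histone list lies at -1.18.

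Mitochondrially encoded genes, the last of the 4 further lists, were lower in 11 of 13, with a median log2 difference of -0.33. The camera adjusted p was 0.0122 at the preset correlation and 0.803 with an estimated correlation. Without KO replicate 1 the median was 0.11, the opposite direction, and the adjusted p 0.953, while the median was -0.87 without WT replicate 1, -0.20 without WT replicate 2 and -0.70 without KO replicate 2, each past the threshold. The call was also lost at a median of -0.33 with no filter (adjusted p = 0.0778), -0.24 with DESeq2 (0.386), -0.36 with the GC and length correction (0.101) and -0.29 without genes that share over 50% of their sequence (0.264). The members did not move together: mt-Nd2 and mt-Nd5, chosen after their values were seen, were above both WT values in KO replicate 1 (855 and 979 FPKM) and below both in KO replicate 2 (412 and 428 FPKM), against 657 and 851 FPKM for mt-Nd2 and 716 and 837 FPKM for mt-Nd5 in WT. In KO replicate 1, mt-Nd3 was at 0.344 FPKM against 534 and 998 FPKM in WT and 822 FPKM in KO replicate 2. mt-Nd4l was at 3.92 FPKM against 1345, 3025 and 1591 FPKM, mt-Co2 at 19.8 FPKM against 965, 1533 and 1727 FPKM, and mt-Atp8 was listed at 1.33e-80 FPKM against 79.5, 449 and 234 FPKM. With edgeR the log2 differences of these 4 lay between -1.97 for mt-Atp8 and -0.62 for mt-Co2, and on FPKM between -4.51 for mt-Nd4l and -2.68 for mt-Co2. KO replicate 1 also held genes of fast skeletal muscle, on a list written after the data were examined: Acta1 was at 176 FPKM there and at most 0.963 FPKM in the other 3 libraries, Ckm at 164 and at most 1.22 FPKM, and Myl1 at 186 and at most 1.92 FPKM. Summed over the table, the T and NK cell markers stood at 0.731 FPKM or less and basal cell markers at 0.975 FPKM or less in each library. Other marker lists stood higher: club cell at 4419 to 6100 FPKM, AT1 cell at 1337 to 1895, fibroblast and smooth muscle at 300 to 513, and neutrophil at 105 to 148. Endothelial cell markers stood at 49.1 to 62.4 FPKM and macrophage markers at 31.8 to 59.9 FPKM. AT2 markers stood at 115790 to 167730 FPKM.

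**Figure D4:**
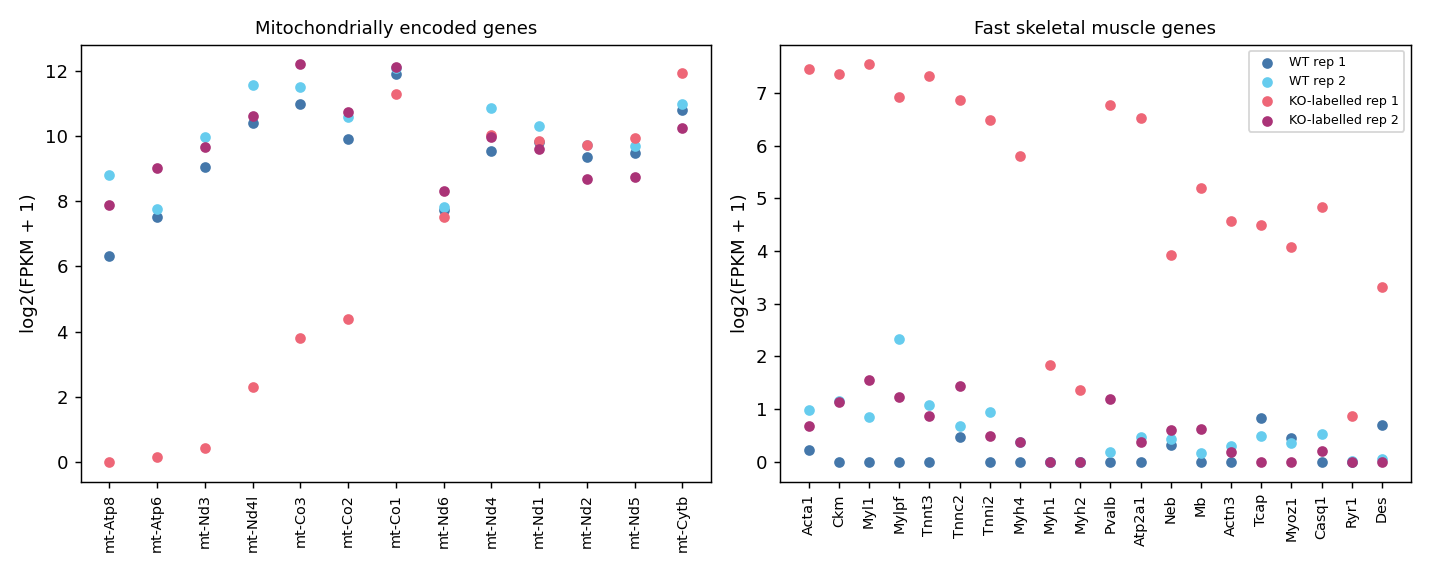
log2(FPKM + 1) of the 13 mitochondrially encoded genes, ordered by the ratio of KO replicate 1 to the other libraries, and of 20 fast skeletal muscle genes, 1 point per gene and library. In KO replicate 1, mt-Nd3 lies at 0.344 FPKM and Acta1 at 176 FPKM, apart from the other 3 libraries.

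The other 25 tested lists had camera adjusted p values from 0.0798 to 0.914. MHC class II genes were lower in 6 of 8 (median -0.22, adjusted p = 0.0798). They were called with no filter at a median of -0.22 (adjusted p = 0.0256), without WT replicate 2 at -0.46 (0.0276) and with edgeR at -0.45 (0.00613). AT1 cell markers were lower in 14 of 22 (median -0.13, adjusted p = 0.129). They were called without KO replicate 1 at a median of -0.21 (adjusted p = 0.0454) and with edgeR at -0.19 (0.00613), and their median was -0.022 without WT replicate 1, -0.019 with the filter at 5 FPKM and -0.076 with equal library totals. MAPK pathway output had a median of -0.11 (adjusted p = 0.143) and was called with no filter at -0.13 (0.0102) and with edgeR at -0.15 (0.0153); its median was -0.24 without WT replicate 2 and -0.20 without KO replicate 1, neither past the threshold. DESeq2 called these 3 lists as well. Ribosomal proteins, with a median of -0.020 (adjusted p = 0.482), were called lower with quantile normalization at -0.10 (0.0314) and without KO replicate 1 at -0.16 (0.000272), and stood at 0.15 without KO replicate 2. Club cell markers, at -0.14 (adjusted p = 0.513), were called lower without WT replicate 2 at -0.45 (0.0114) and stood at 0.073 without WT replicate 1, 0.070 without KO replicate 1 and -0.31 without KO replicate 2. Genes of the epithelial-mesenchymal transition, at 0.22 (adjusted p = 0.513), were called higher without WT replicate 1 at 0.24 (0.0103) and stood at -0.073 without WT replicate 2, -0.036 without KO replicate 1, 0.34 without KO replicate 2 and 0.012 with edgeR. Immediate early genes, at 0.058 (adjusted p = 0.483), were called lower without WT replicate 2 at -0.24 (0.0229) and without KO replicate 1 at -0.21 (0.0454), and stood at 0.22 without WT replicate 1. Genes of mouse lung adenocarcinoma progression, at -0.21 (adjusted p = 0.143), were called lower with the GC and length correction at -0.31 (0.0460), and stood at -0.14 without KO replicate 1, -0.33 without KO replicate 2, -0.0080 with no filter and -0.056 with edgeR. With an estimated correlation the adjusted p of each call in this paragraph, DESeq2's apart, lay between 0.659 and 0.987; DESeq2 was not run that way.

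DNA replication and S phase genes were split, 14 higher and 14 lower (adjusted p = 0.513), as were mitosis genes, 5 higher and 7 lower (adjusted p = 0.628). With no filter on low values 27 of 40 mitosis genes were lower and 13 higher, with a median of -0.12 and a camera adjusted p of 0.0102, and the adjusted p was 0.659 with an estimated correlation; with edgeR the median was -0.35 over 20 genes (adjusted p = 0.198). Partners and reported substrates of the FBXO45 ligase were higher in 8 of 11 (adjusted p = 0.513). For AT2 markers, p53 targets, DNA replication and immediate early genes the median was above 0 where the mean and the test were below, and for the Krt8-high transitional state the median and the test were below 0 and the mean above.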

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

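edgeR on recovered fragments, the GC and length correction, both ways of leaving out genes, and the estimated correlation together with any other setting were chosen only after the data were examined. The count of 0 changed genes was 7 with DESeq2 (1 higher, 6 lower), and between 0 and 134 on leaving out 1 library (0 to 72 higher, 0 to 62 lower); the 134 came without KO replicate 2, where the lone KO library is assumed to vary like the WT pair, and in 72 of them KO replicate 2 lay on the same side of both WT libraries. The 5 shifted lists were 3 without genes that share a locus, 0 with an estimated correlation, 0 with fry, and 3 to 7 on leaving out 1 library. The histone median of -1.18 kept its direction, and its camera call, in each alternative refit, and was no longer past the threshold with an estimated correlation (adjusted p = 0.803) or fry (0.451), which keep the median at -1.18. The Fbxo45 difference ranged from -0.20 to 0.46 on leaving out 1 library. The replicate numbers pair 2 libraries per group only by number: the correlation of their differences was 0.03, the replicate block called 0 genes (lowest adjusted p = 0.072) and 4 lists, and among lists it lost the call of Wnt and Notch targets. The cause of these and the following changes was not tested.

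The following list medians and gene differences on the log2 scale changed sign or came to exactly 0, none of them past the threshold in the main test. With no filter on low values they were -0.11 for macrophage markers, -0.10 for homologous recombination, -0.00099 for senescence, -0.015 for NRF2, -0.033 for YAP and TEAD targets and 0.0055 for ribosomal proteins. With the filter at 5 FPKM they were -0.10 for homologous recombination and 0.028 for the interferon response. With median-of-ratios scaling they were -0.014 for AT2 cell markers, -0.022 for DNA replication and -0.027 for Sftpa1. With quantile normalization they were 0 for AT2 cell markers, -0.0036 for macrophage markers, -0.052 for NRF2, 0 for Sftpc and 0.084 for Abca3. With equal library totals they were 0.041 for the Krt8-high state, 0.036 for ribosomal proteins, 0.039 for Cdkn1a and 0.054 for Abca3. With edgeR they were 0.034 for the Krt8-high state, -0.050 for p53 targets, -0.026 for homologous recombination, 0.0017 for the interferon response, -0.084 for YAP and TEAD targets, 0.043 for ribosomal proteins, -0.050 for Mdm2, 0.086 for Cdkn1a and -0.011 for Sftpa1. With size factors in place of TMM they were 0.040 for the Krt8-high state, -0.043 for p53 targets, -0.019 for homologous recombination, 0.0093 for the interferon response, -0.078 for YAP and TEAD targets, 0.049 for ribosomal proteins, -0.043 for Mdm2, 0.090 for Cdkn1a and -0.0046 for Sftpa1. With DESeq2 they were 0.038 for the Krt8-high state, -0.045 for p53 targets, -0.021 for homologous recombination, 0.017 for the interferon response, -0.079 for YAP and TEAD targets, 0.048 for ribosomal proteins, -0.046 for Mdm2, 0.087 for Cdkn1a and -0.0063 for Sftpa1. With the GC and length correction they were -0.0019 for AT2 cell markers, 0.0079 for the Krt8-high state, -0.057 for macrophage markers, -0.091 for DNA replication, -0.042 for homologous recombination, 0.10 for ribosomal proteins, -0.10 for Sftpa1 and 0.0055 for Abca3. Without genes that share a locus they were -0.057 for YAP and TEAD targets.

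On leaving out 1 library the ranges were -0.13 to 0.12 for Abca3, -0.36 to 0.33 for Cdkn1a, -0.042 to 0.23 for Fbxo46, -0.14 to 0.17 for Sftpa1, -7.57 to 0.30 for mt-Atp8, -5.87 to 0.51 for mt-Co2, -9.09 to 0.17 for mt-Nd3, -0.065 to 0.060 for AT2 cell markers, -0.10 to 0.080 for DNA replication, -0.13 to 0.14 for the Krt8-high state, -0.061 to 0.15 for NRF2, -0.16 to 0.17 for YAP and TEAD targets, -0.45 to 0.073 for club cell markers, -0.16 to 0.15 for ribosomal proteins, -0.073 to 0.34 for epithelial-mesenchymal transition, -0.10 to 0.81 for fibroblast markers, -0.24 to 0.22 for immediate early genes, -0.14 to 0.50 for macrophage markers, -0.87 to 0.11 for mitochondrially encoded genes, -0.12 to 0.0070 for mitosis, -0.17 to 0.046 for replacement histones and -0.12 to 0.20 for senescence. Of the values under alternatives, 1463 kept direction and side of the threshold, 88 changed sign or came to 0, 25 were no longer past the threshold, 31 came to pass it and 13 counts moved by over 1.5 times. In the simulation limma called 7.41% of 2-fold changes, so changes of that size may go unseen. Its genes all had the same dispersion, so larger changes may go unseen in the data as well. Hist1h3f, at 11.9 and 9.53 FPKM in WT and 0.746 and 1.81 FPKM in the KO-labelled libraries, did not pass over all genes. Isoform choice and a test of the authors' own could not be run, since the table holds neither.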

Other observations

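The test on randomly drawn lists matched on GC content, length and level was set before its result was seen, and the list tests with no filter on low values were planned; the other tests in this part were chosen only after the result was seen, among them the stricter matches, S phase and mitosis genes as 1 set, and an estimated correlation under other settings. Terms of the table's own annotation were tested on the same genes and libraries, so they add no separate support. Of 1364 biological process terms camera called 6, and of 267 pathways 2, at the preset correlation, and 0 of either with an estimated correlation. The pathway for systemic lupus erythematosus, whose members include histone genes, was lower in 44 of 60 (median log2 difference -0.38, adjusted p = 2.29e-09; 0.99 with an estimated correlation).

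For the lower replication-dependent histones, a trend on GC content and length as the whole cause is argued against: after correction, the 32 members with a GC value had a median of -0.80 against -1.02 before (camera adjusted p = 1.05e-12; 0.776 with an estimated correlation). Likewise 0 of 10000 lists of other genes matched on GC, length and level were as low, the lowest being -0.54, although the matched genes were longer (median 1135 against 625 bases); a stricter match on length (813 bases), and one that added shared sequence (median 19.9% against 31.4%, 886.5 bases), also gave 0, so no match reached the members' own length or sharing. Genes of the random lists were drawn singly, whereas the histones may vary together (estimated correlation 0.196). The 0 of 10000 is therefore not a chance rate for lists whose members vary together. Fewer cycling cells as a cause were not settled. The 40 S phase and mitosis genes fell less than the histones, with a median of -0.038 (SD over genes 0.374). Over all 81 with no filter the median was -0.077 (SD 0.381) where the histones stood at -0.79. Log2(FPKM + 1) understates changes of low genes, though, and only 12 of 40 mitosis genes passed the filter. Of mitosis genes alone 27 of 40 were lower with no filter (median -0.12, camera adjusted p = 0.0102, and 0.659 with an estimated correlation). With edgeR the medians were 0.064 for S phase genes (SD 0.694), -0.35 for mitosis genes (SD 0.470) and -0.87 for the histones (SD 0.893). Reads shared between histone copies may account for part of the histone difference and stay open, with values on both sides. The 6 members with at most 5% of shared sequence, 5 of them lower, had a median of -0.42 and stood at 0.007 in KO replicate 2. There Hist1h4d, Hist4h4 and Hist1h1d were below both WT values, and Hist2h2be, Hist2h4 and Hist1h1a were not. The 7 with 5 to 25% were all lower (-0.79 and -0.69 in KO replicates 1 and 2). Without genes that share over 50% of their sequence 21 of 22 members were lower (median -0.89, camera adjusted p = 4.94e-13, and 0.811 with an estimated correlation). Reads moved between members would leave the family's total unchanged. That total stood at 430.8 and 437.1 CPM in WT and at 179.8 and 270.3 CPM in KO replicates 1 and 2, which argues against such moves as the whole cause. Loss of shared reads would lower the total and was not excluded. The 50 nuclear genes with over 90% of shared sequence, Hist1h2ao among them, were set against their mean in the other libraries. The share under 0.2 times that mean was 24% in KO replicate 1 and 16% in KO replicate 2. It was 6% in WT replicate 1 and 4% in WT replicate 2. An effect of the genotype stays open as well; the other 2 ways to split the 4 libraries gave histone medians of 0.28 and -0.42.

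In KO replicate 1 some mitochondrially encoded genes lay near 0. Less mitochondrial RNA in that library is argued against, since the members with at most 5% of shared sequence stood at a median ratio of 1.14 to the other 3 libraries. The near-0 genes mt-Atp6, mt-Nd3, mt-Nd4l, mt-Co3 and mt-Co2 share between 96.6% and 100% of their sequence with other annotated transcripts. The near-0 gene mt-Atp8 shares 0% with annotated transcripts, but copies without an annotated transcript were not searched. On the mitochondrial genome mt-Atp8 (7766 to 7969) follows mt-Co2 (7013 to 7696) and overlaps the start of mt-Atp6 (7927 to 8607). The genes mt-Atp6 and mt-Co3 were chosen after their values were seen. Loss of reads that match a second transcript could be involved and cannot be told apart from other causes: the 50 nuclear genes with over 90% of shared sequence had a median ratio of 0.794, between the bounds set for either answer, and 24% of them lay under 0.2, against 16% in KO replicate 2, 6% in WT replicate 1 and 4% in WT replicate 2. The mitochondrial genes together stood at 15621 CPM in KO replicate 1, against 15004 and 20120 CPM in WT replicates 1 and 2 and 16589 CPM in KO replicate 2. By fragments, a net loss from the set was thus not seen. Their summed FPKM was lowest in KO replicate 1, at 10511 against 14031, 20667 and 18247.

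RNA of skeletal muscle in KO replicate 1 is a candidate explanation for its muscle genes. There, 19 of 20 fast skeletal muscle genes were at 1 FPKM or more and 10 or more times their highest value elsewhere. The same held for 3 of 10 cardiac genes. A sort for AT2 cells is meant to remove muscle cells, and how far it did so was not tested. If both KO-labelled libraries carry 1 genotype, that genotype as the cause is argued against by KO replicate 2, where the list's median was 0.346 FPKM against 45.2 FPKM in KO replicate 1, 0 in WT replicate 1 and 0.362 in WT replicate 2. The genotype field of KO replicate 2 names Fbxo46, so this rests on the titles.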
